A study of Mus musculus with 6 samples.

How the data were processed

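High-throughput genome-wide translocation sequencing (HTGTS) maps DNA junctions formed by one fixed break region, the bait, with the rest of the genome. Here the bait was the switch region Sμ of the mouse immunoglobulin heavy chain locus (IgH). Per the labels' protocols, splenic B cells lacking CD43 were cultured for 4 days with anti-CD40 (1 ng/mL) and IL-4 (20 ng/mL), a stimulus for class switching to IgG1 and IgE. Genomic DNA was linearly amplified from a biotinylated Sμ primer, nested PCR followed, and AflII digestion removed unrearranged product before MiSeq sequencing. The mice were of the 129 strain, per the labels.

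The submitters' processing notes name Bowtie2 and the mm9 build, and no version of Bowtie2 is given in the sources used here. Per the series' design text, the mm9 segment from JH4 to the last Cα exon was exchanged for 129 sequence, so coordinates inside IgH belong to that modified build (mm9sr) and were not converted. The deposited values of other kinds are the junction coordinate, the orientation and the read positions at which bait and prey alignments end, listed per junction by the authors. The deposited counts are whole numbers of junctions per bin and region, and of bait mutations and bait bases sequenced, made by the authors. Each junction in the lists carries a mark for duplicates, and 0 of the listed IgH junctions had that mark set. Per library, 2.56% to 6.19% of IgH junctions had a match in another library. Such matches shared coordinate, orientation, bait alignment position and the distance between the 2 alignments. Whether they are separate events was not tested. The lists of wild-type replicate 1 have 29 columns, against 32 in those of the other 5 libraries. Read names place all 6 libraries in 1 sequencing run, so no run batch separates the groups.

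The 6 libraries form 3 groups of 2: wild type, ATM knockout (ATM KO) and ATM RX/RX. Nothing in the labels used here ties each library to a separate animal. P-values between groups therefore rest at most on the spread between these libraries, which may be partly technical. Those of edgeR also pool that spread over the classes or bins of a family, which are not independent of each other. Those of Fisher's exact tests between single libraries cover counting error only. Listed junctions were tallied by the authors' regions Sμ, Sγ1, Sε and other IgH. Some lines of the lists are empty: 14 IgH lines in ATM KO replicate 2 and 4 in each ATM RX/RX library. These were not analysed here. For Sμ, Sγ1 and Sε, listed plus empty lines equalled the authors' region counts in all 6 libraries. Lists of junctions outside IgH were used from 4 libraries, in which 115, 19, 75 and 36 lines were empty. Totals outside IgH were therefore taken from the authors' summary counts, and no comparison by chromosome was made.

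The distance between the bait and prey alignments on the read gave the junction structure: a positive distance is an insertion, 0 is a blunt joint, and an overlap is microhomology of that length. Orientation was used as deposited. Minus-orientation junctions in a switch region include the deletional joins, though orientation alone does not exclude joins between chromosomes among them. A plus-orientation junction corresponds to an inversion or a join between chromosomes. Shares carry exact Clopper-Pearson intervals at the 95% level for single libraries. PCR reads without molecular identifiers are not independent molecules, so intervals and limits for a count of 0 (3 counts of the total) cover counting error only.

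Group means were compared with a two-sided exact permutation test, whose smallest p with 2 against 2 libraries is 0.3333 and which cannot reach 0.05. Fisher's exact tests between single libraries compare those libraries, not the genotypes. Their p-values were adjusted together over 384 tests by the Benjamini-Hochberg method. Counts of junctions were also tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, 1 common negative binomial dispersion per family, no trend, all 6 libraries in 1 fit, genotype only). The families were 10 region and orientation classes with the library total as offset, 24 structure classes within Sμ, Sγ1 and Sε with the region total as offset, and 46 bins of 500 bp with at least 10 junctions. The Benjamini-Hochberg adjustment ran within each family and comparison, at a threshold of 0.05. The classes family holds 8 classes inside IgH, chromosome 12 outside IgH, and the other chromosomes together. The design called for counts by chromosome, which the lists used here did not allow.

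The edgeR step was tested on 40 simulated data sets per setting of the ATM RX/RX against wild-type comparison. With 4-fold changes it recovered 90.0% of changed classes among 10, 84.0% among 24 structure classes and 59.2% among 46 bins. With 2-fold changes these were 35.0%, 47.5% and 15.0%. With no change, 6.0%, 3.9% and 3.5% of features had an unadjusted p under 0.05. The simulations used the dispersions edgeR had fitted, 0.0490, 0.00108 and 0.0111, and so do not test them. A dispersion estimated per class was tried first but stopped with an error on a simulated table, before any real result was seen, and the common dispersion took its place.

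Prey sequences and primers were matched to chromosome 12 of mm9 (NCBIM37) with blastn 2.17.0 at an E-value of at most 1e-05 for prey. Genes came from the GENCODE annotation of that build, in which the constant genes of γ3, γ2b and ε carry placeholder or shortened names. They were named by their order along the locus. A prey was given to a constant gene if it lay in the gene or up to 15 kb upstream of it. Junctions off chromosome 12 were placed in genes by their mm9 coordinate. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

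The rule for named items, fixed before the data were examined, took Sμ, Sγ1 and Sε always, other classes and bins past the threshold, off-target genes with at least 2 junctions, and any other gene with at least 3 junctions from at least 2 libraries. Genes were first counted by distinct coordinates and then, after those counts were seen, by listed junctions, which added Gpr84. The fixed lists were the acceptors of this stimulus (Sγ1, Sε), the acceptors it does not target (Sγ3, Sγ2b, Sγ2a/c, Sα), known off-target genes of the deaminase AID, and the other antigen receptor loci. Igk and Igl were counted with the last list only. Alternatives covered normalisation, DESeq2 1.42.0, count filters, denominators, repeated coordinates, orientation, bin size, microhomology length, each library left out and a replicate block. A second summary sheet of ATM KO replicate 2, relative-frequency graphs and lists of long insertions were not used in the comparisons.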

Results

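Junctions between an Sμ bait and the rest of the genome were mapped by HTGTS in activated B cells of 3 genotypes, with 2 libraries each. ATM is the kinase that signals DNA double-strand breaks, and class switching joins such breaks between Sμ and a downstream switch region. The RX allele lacks the FATC domain at the end of the protein. The comparisons ask whether B cells with this allele repair switch breaks as wild-type cells do, and how they compare with cells that lack ATM. The files do not measure the Atm gene or its product. Depth was 904 and 507 junctions in the wild-type libraries, 414 and 1849 in ATM KO, and 1233 and 701 in ATM RX/RX. Of these, 721, 391, 298, 1446, 859 and 521 lay in IgH by the authors' counts, in the same order.

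The nested bait primer matched mm9 at 1 place, chromosome 12 from 114664889 to 114664909 on the minus strand. That place is 3948 bp upstream of the annotated Ighm gene, outside any annotated exon or gene. In the authors' modified build, the Sμ list covers chromosome 12 from 114661501 to 114671500, the Sγ1 list 114558001 to 114588000, and the Sε list 114507001 to 114517000. Sγ1 and Sε precede the constant genes of IgG1 and IgE, the isotypes that anti-CD40 and IL-4 induce.

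Sε took a far smaller share of IgH junctions in ATM RX/RX than in wild type. These are shares of the junctions recovered, and joins per cell were not measured. Sε held 36.4% ± 11.3 (SD, n = 2) of IgH junctions in wild type and 6.40% ± 3.26 (SD, n = 2) in ATM RX/RX. Junctions within Sμ, which are internal to the bait region, made up 34.3% ± 1.80 (SD, n = 2) in wild type and 58.9% ± 5.87 (SD, n = 2) in ATM RX/RX. As percent of all listed junctions this Sμ difference was 15.4 points, against 24.6 as percent of IgH. The Sγ1 share was 26.3% ± 7.62 (SD, n = 2) and 29.5% ± 2.34 (SD, n = 2), a difference smaller than the spread between the wild-type libraries. Among Sγ1 and Sε junctions together, Sε made up 57.6% ± 14.6 in wild type and 17.3% ± 6.38 in ATM RX/RX (SD, n = 2 each). For Sε and for Sμ, both ATM RX/RX libraries lay on the same side of both wild-type libraries, which happens by chance in 33.3% of splits of 2 against 2. The exact permutation p was 0.3333 for each, the smallest possible. All 4 pairs of single libraries differed in Sε share by Fisher's exact test, with adjusted p from 1.4e-85 to 1.8e-13.

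In ATM KO the Sε share was likewise lower and the Sμ share higher than in wild type. Its Sε share was 7.32% ± 2.29 (SD, n = 2), its Sμ share 62.2% ± 0.820 (SD, n = 2) and its Sγ1 share 23.0% ± 0.743 (SD, n = 2). Sε made up 23.9% ± 5.15 (SD, n = 2) of Sγ1 and Sε junctions. The exact permutation p against wild type was 0.3333 for Sε and Sμ and 1.0 for Sγ1. The sign of the Sγ1 difference depended on the wild-type library. Without wild-type replicate 1 it was -8.71 points in ATM KO and -2.22 in ATM RX/RX, and without wild-type replicate 2 it was 2.07 and 8.55. Fisher's exact tests of the 4 pairs of single libraries gave adjusted p from 1.9e-75 to 3.6e-14 for Sε.

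Both mutant groups were compared with the same wild-type libraries, so their departures from wild type share chance values. Between ATM RX/RX and ATM KO, the Sε share differed by -0.923 percentage points, less than the spread of 2.82 points (pooled SD), and the exact permutation p was 0.667. Its sign turned without ATM KO replicate 2 (0.694 points) and without ATM RX/RX replicate 1 (1.38 points). The Sγ1 share was 6.48 points higher in ATM RX/RX, with no overlap between the groups and an exact permutation p of 0.3333, but by 3.96 points as percent of all listed junctions. In single libraries, Sε ranged from 28.4% (95% Clopper-Pearson interval 24.0 to 33.1) to 44.4% (40.7 to 48.1) in wild type. The highest mutant library was at 8.94% (7.51 to 10.5).

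**Figure D1:**
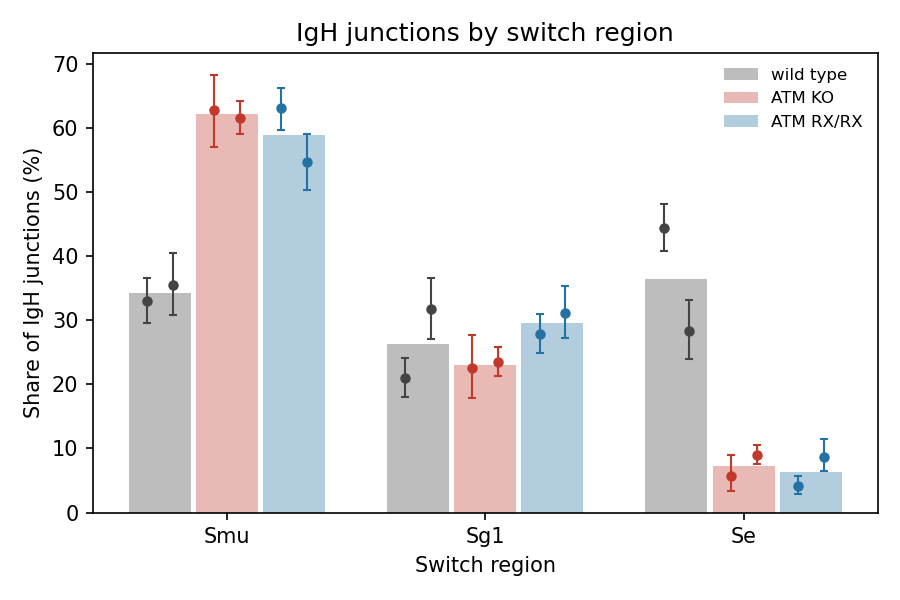
Share of IgH junctions (%, y axis) in Sμ, Sγ1 and Sε (x axis; written Smu, Sg1, Se) for wild type, ATM KO and ATM RX/RX. Points are single libraries with 95% Clopper-Pearson intervals and bars are group means; for Sε the 4 mutant libraries reach at most 8.94%, against at least 28.4% in wild type.

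Junction counts by region and orientation showed where the groups parted. Relative to all junctions, minus-orientation Sε junctions, which include the deletional joins that yield IgE, fell in ATM RX/RX by 2.85 ± 0.58 (SE) on the log2 scale, with an edgeR adjusted p of 0.0258. Plus-orientation Sμ junctions rose 2.60-fold (log2 1.38 ± 0.20 SE, edgeR adjusted p = 0.0138). These were the 2 of 10 classes past the threshold. In ATM KO, 3 of 10 classes passed. Minus-orientation Sε junctions fell by 2.36 ± 0.56 (SE) on the log2 scale (edgeR adjusted p = 0.0318), and plus-orientation Sμ junctions rose 2.94-fold (log2 1.55 ± 0.20 SE, edgeR adjusted p = 0.00829). Plus-orientation junctions elsewhere in IgH rose 4.31-fold (log2 2.11 ± 0.40 SE, edgeR adjusted p = 0.0205). Between ATM RX/RX and ATM KO, edgeR called 0 of 10 classes, with 0 at an unadjusted p under 0.05, and DESeq2 called 0. The calls rest on few libraries. Without wild-type replicate 1 no class passed in either comparison with wild type, and none passed without ATM RX/RX replicate 1 or without ATM KO replicate 2 in that group's comparison. Without ATM KO replicate 1, 1 class passed in ATM KO. A block for the replicate number left 0 classes in ATM KO. The ATM KO call for minus-orientation Sε stayed past the threshold in 4 of 10 alternative settings, and its sign turned in 0. Of these settings 1, the filter of at least 10 junctions, removed no class and repeats the main fit. TMM factors left 1 class in ATM RX/RX, the fall of minus-orientation Sε, and the rise of plus-orientation Sμ was no longer called. IgH totals as the offset gave 5, with the classes outside IgH still among the 10 tested though they are no part of that total.

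Joins in the plus orientation took a larger share in both mutants. Over Sμ, Sγ1 and Sε they made up 15.2% ± 1.84 (SD, n = 2) in wild type, 37.4% ± 3.72 (SD, n = 2) in ATM RX/RX and 35.8% ± 4.76 (SD, n = 2) in ATM KO. The mix of regions enters this pooled share, as Sε, with few plus-orientation joins in wild type, was rarer in the mutants. The pooled difference from wild type exceeded that of every single region in both mutants. Within Sμ the shares were 24.6% ± 0.233, 40.4% ± 3.70 and 41.2% ± 3.80 (SD, n = 2 each). Without junctions near or upstream of the bait, a setting chosen after the data were seen, the Sμ difference from wild type went from 15.8 to 9.74 percentage points in ATM RX/RX and from 16.6 to 14.1 in ATM KO. For the 3 regions together and for Sμ, mutant and wild-type libraries did not overlap, and the exact permutation p was 0.3333. Fisher's exact tests of single libraries gave adjusted p from 4.6e-23 to 2.4e-11 for ATM RX/RX over the 3 regions, and from 6.4e-26 to 1.2e-06 for ATM KO. In Sγ1 the plus share was 19.4% ± 9.14 in wild type, 36.1% ± 1.69 in ATM RX/RX and 30.6% ± 9.55 in ATM KO (SD, n = 2 each), and ATM KO overlapped wild type. Without wild-type replicate 2 the Sγ1 difference of ATM RX/RX was 10.2 points, against 16.7 with it. In Sε the counts were too few for a firm statement. ATM KO replicate 1 had 0 of 17 Sε junctions in the plus orientation, which allows a share of up to 17.6%, and ATM KO replicate 2 had 15 of 128. ATM RX/RX had 10 of 35 and 3 of 45, and wild type 19 of 320 and 2 of 111. ATM RX/RX and ATM KO differed by 1.56 percentage points over the 3 regions, less than the pooled SD of 4.27 points, and the sign turned without ATM KO replicate 1 (-1.80) or ATM RX/RX replicate 1 (-1.07).

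**Figure D2:**
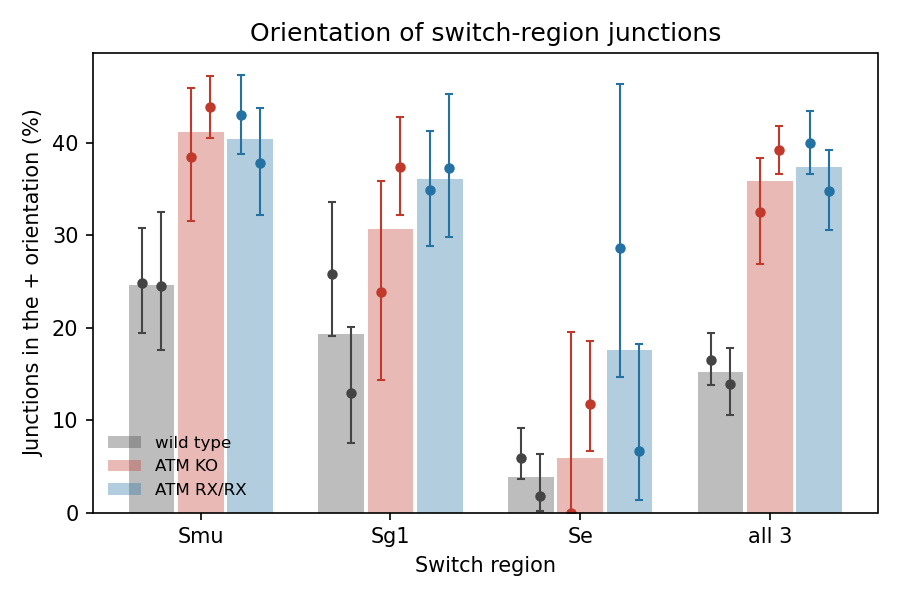
Share of junctions in the plus orientation (%, y axis) within Sμ, Sγ1, Sε and all 3 regions together (x axis) for the 3 genotypes. Points are single libraries with 95% Clopper-Pearson intervals and bars are group means; over the 3 regions both wild-type libraries lie at or below 16.5% and the 4 mutant libraries at or above 32.5%.

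Blunt joints within Sμ were fewer in both mutants, and those in Sγ1 were not called. Blunt joints within Sμ fell from 24.7% ± 2.44 (SD, n = 2) in wild type to 10.3% ± 0.412 (SD, n = 2) in ATM RX/RX and 11.5% ± 0.317 (SD, n = 2) in ATM KO. The log2 fold changes were -1.30 ± 0.23 (SE, edgeR adjusted p = 9.7e-06) and -1.12 ± 0.22 (SE, edgeR adjusted p = 5.8e-05). For the structure classes edgeR fitted a coefficient of variation of only 3.29% between libraries. The edgeR p-values of these classes therefore rest largely on counting error, with the spread pooled over classes that depend on each other. In Sγ1 blunt joints made up 18.7% in wild type, 13.0% in ATM RX/RX (edgeR adjusted p = 0.111) and 18.0% in ATM KO (edgeR adjusted p = 0.647). In Sε they were not called in ATM KO either (19.0% against 25.6%, edgeR adjusted p = 0.378). Microhomology of 1 bp or more was present in 57.8% ± 0.304 of wild-type Sμ junctions, 72.4% ± 0.570 in ATM RX/RX and 69.4% ± 3.99 in ATM KO (SD, n = 2 each). In percentage points the Sμ difference depended on the length asked for. At 4 bp or more it was 5.29 points in ATM RX/RX, against 14.6, and 6.12 in ATM KO, against 11.6. As a ratio to wild type it did not shrink, at 1.36 in ATM RX/RX, against 1.25, and 1.42 in ATM KO, against 1.20. Fisher's exact test at 4 bp or more, with fewer such junctions, separated 0 of 4 library pairs in either comparison. Over Sγ1 and Sε together the shares were 60.0% ± 1.74, 74.7% ± 2.04 and 66.2% ± 2.75 (SD, n = 2 each). For both measures the exact permutation p of each mutant against wild type was 0.3333. By Fisher's exact test over Sγ1 and Sε, 4 of 4 library pairs differed between ATM RX/RX and wild type (adjusted p from 1.4e-05 to 0.0315), 1 of 4 between ATM KO and wild type, and 0 of 4 between the mutants. At 2 bp or more the differences from wild type over Sγ1 and Sε were 23.2 points in ATM RX/RX, against 14.7, and 15.6 in ATM KO, against 6.19. The mix of Sγ1 and Sε differs between the groups, so the regions are also given singly, with fewer junctions in each test. In Sγ1 the shares were 64.7% ± 5.39, 74.6% ± 2.69 and 67.7% ± 4.98, and in Sε 55.5% ± 3.29, 74.9% ± 0.898 and 62.4% ± 3.22 (wild type, ATM RX/RX, ATM KO; SD, n = 2 each). Fisher's exact test separated 1 of 4 pairs of ATM RX/RX and wild type in each region (adjusted p from 0.00692 to 0.706 in Sγ1 and from 0.0413 to 0.154 in Sε) and 0 of 4 for ATM KO. In Sγ1 ATM KO overlapped wild type, with an exact permutation p of 0.667.

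In ATM RX/RX, 7 of 24 structure classes passed. Microhomology of 3 bp rose in Sμ (2.28-fold, edgeR adjusted p = 0.00059), Sγ1 (2.38-fold, edgeR adjusted p = 0.00184) and Sε (2.21-fold, edgeR adjusted p = 0.0473). The Sε call stayed past the threshold in 3 of 10 alternative settings, against 7 for Sμ and 9 for Sγ1. In these tallies 1 of the 10 settings, the filter of at least 10 junctions, removed no class and so repeats the main fit. Blunt joints in Sε fell by 2.75 on the log2 scale (edgeR adjusted p = 0.00059), 1 bp insertions in Sμ by 1.39 (edgeR adjusted p = 0.00511) and 1 bp microhomology in Sγ1 by 0.939 (edgeR adjusted p = 0.00315). The Sε value rests on few junctions: 2 of 35 and 1 of 45 were blunt in the ATM RX/RX libraries. The counts were 80 of 320 and 29 of 111 in wild type, and 3 of 17 and 26 of 128 in ATM KO. In ATM KO, 5 classes passed. Beside blunt joints, Sμ insertions of 2 bp or more rose 1.85-fold (edgeR adjusted p = 0.0144) and Sμ microhomology of 3 bp rose 1.90-fold (edgeR adjusted p = 0.0144). Insertions of 1 bp in Sμ fell by 0.983 on the log2 scale (edgeR adjusted p = 0.0497), as did 1 bp microhomology in Sγ1 by 0.694 (edgeR adjusted p = 0.0468). These last 2 calls each stayed past the threshold in 1 of 10 alternative settings, which was the filter that repeats the main fit. Sμ insertions of 2 bp or more stayed past it in 2 of 10 and Sμ microhomology of 3 bp in 5 of 10. Blunt Sμ joints in ATM KO did so in 8 of 10. Blunt Sε joints alone differed between the mutants, at 3.97% in ATM RX/RX and 19.0% in ATM KO (edgeR adjusted p = 0.0401), and this call was lost without any 1 of the 6 libraries. DESeq2, which fitted a larger dispersion, called 0 structure classes in all 3 comparisons. With each library of the comparison left out in turn, edgeR called 3 to 9 classes in ATM RX/RX and 0 to 3 in ATM KO. The ATM RX/RX count was 3 without wild-type replicate 2, and 4 without wild-type replicate 1 or without ATM RX/RX replicate 1. In ATM KO it was 0 without wild-type replicate 1, 1 without wild-type replicate 2, 3 without ATM KO replicate 1 and 2 without ATM KO replicate 2.

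Mean microhomology length over Sγ1 and Sε was 2.19 ± 0.0677 bp in wild type, 2.93 ± 0.0856 bp in ATM RX/RX and 2.89 ± 0.103 bp in ATM KO (SD, n = 2 each). Counting blunt joints as length 0, the means were 1.59 ± 0.00325, 2.55 ± 0.141 and 2.26 ± 0.0337 bp. Without blunt joints, the lengths in Sγ1 alone were 2.37 ± 0.347, 3.03 ± 0.0324 and 2.99 ± 0.151 bp (SD, n = 2 each). In Sε alone they were 2.10 ± 0.0773, 2.59 ± 0.466 and 2.54 ± 0.119 bp (SD, n = 2 each). There ATM RX/RX replicate 2 stood at 2.26 bp, near the 2.15 bp of wild-type replicate 2. The mix of the 2 regions enters the pooled lengths: the ATM RX/RX difference was 0.748 bp pooled, 0.654 in Sγ1 and 0.496 in Sε. Within Sμ the lengths were 2.64 ± 0.0714, 2.94 ± 0.00941 and 2.91 ± 0.0477 bp (SD, n = 2 each). Neither mutant overlapped wild type in these lengths, and the exact permutation p was 0.3333.

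**Figure D3:**
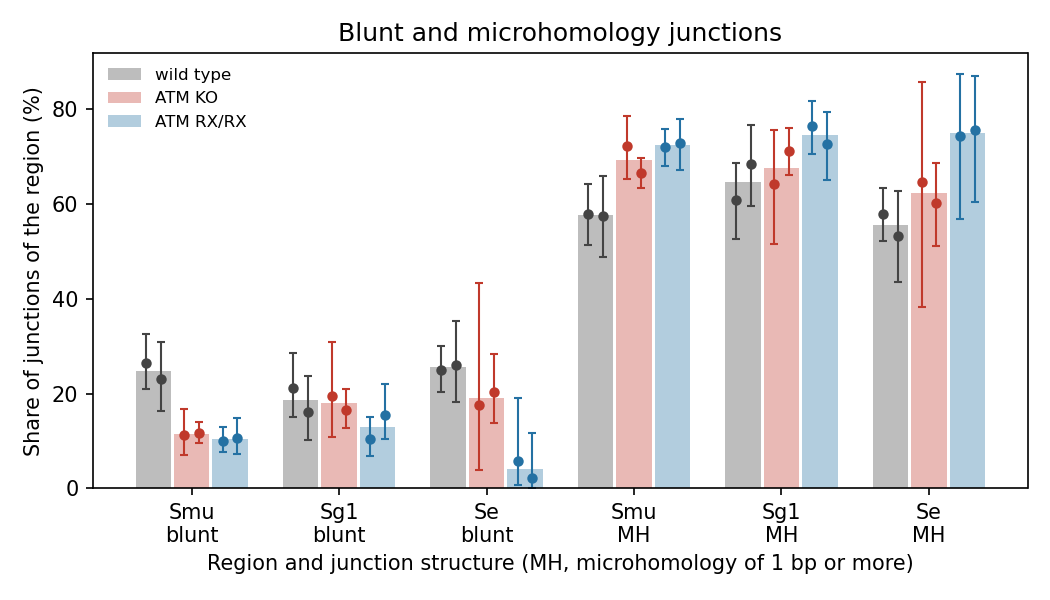
Share of junctions (%, y axis) that were blunt or had microhomology of 1 bp or more, by switch region (x axis), in the 3 genotypes. Points are single libraries with 95% Clopper-Pearson intervals and bars are group means; blunt joints in Sμ stand at 24.7% in wild type, 11.5% in ATM KO and 10.3% in ATM RX/RX.

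Within the regions, few positions passed the threshold. Of 46 bins, 3 passed in ATM RX/RX and 2 in ATM KO, all in Sμ. In edgeR, 9 bins had an unadjusted p under 0.05 in each comparison with wild type. The simulations recovered 15.0% of bins changed 2-fold, so such shifts can be missed. The bin from 114669501 to 114670000, on the upstream side of the bait, held 0.930% of wild-type Sμ junctions on average, 4.00% in ATM RX/RX (edgeR adjusted p = 0.0184) and 3.34% in ATM KO (edgeR adjusted p = 0.0494). The bin from 114663501 to 114664000 held 0 wild-type junctions and 2.23% of those in ATM RX/RX, at least 2.58-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.0184). The bin from 114667501 to 114668000 fell from 19.1% to 8.92% in ATM RX/RX (edgeR adjusted p = 0.0142). In ATM KO the bin from 114668501 to 114669000 rose from 9.54% to 16.9% (edgeR adjusted p = 0.0494). Between the mutants edgeR called 0 bins, with 1 at an unadjusted p under 0.05, and DESeq2 called 0. With bins of 1000 bp, with DESeq2, with the replicate block, or without wild-type replicate 1, no bin passed in either comparison with wild type. The same held for ATM RX/RX without its replicate 1, and for ATM KO without wild-type replicate 2 or its own replicate 2, or without either ATM RX/RX library, which share the fit. Without replicate 2 of its own group 1 bin passed in ATM RX/RX, without wild-type replicate 2 there were 2, and 6 passed in ATM KO without its replicate 1.

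Junctions in the Ighm gene and downstream of it took a larger share of IgH junctions in the mutants, a comparison chosen after the data were seen. In mm9 the interval runs on chromosome 12 from 114614444, just past the 15 kb window upstream of Ighg3, to 114660941, the start of the Ighm gene in its direction of transcription. It held 1 of 721 and 1 of 391 wild-type IgH junctions, 13 of 298 and 50 of 1432 in ATM KO, and 26 of 855 and 20 of 517 in ATM RX/RX. The group means were 0.197% ± 0.0828 in wild type, 3.93% ± 0.616 in ATM KO and 3.46% ± 0.585 in ATM RX/RX (SD, n = 2 each). Fisher's exact test separated all 4 library pairs in each comparison, with unadjusted p from 2.7e-07 to 0.00061 for ATM RX/RX and from 2.8e-08 to 0.000136 for ATM KO, and the exact permutation p was 0.3333. The prey of all 111 had no equally good match outside the interval on that chromosome. The 53 inside the Ighm gene and 2 beyond it belong to the authors' Sμ list and are also counted among the Sμ junctions above, and the other 56 lie outside that list. Beyond the Ighm gene alone, both wild-type libraries had 0 junctions, which allows shares of up to 0.416% and 0.767%, against 1.61% ± 0.458 in ATM RX/RX and 2.22% ± 0.180 in ATM KO (SD, n = 2 each).

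**Figure D4:**
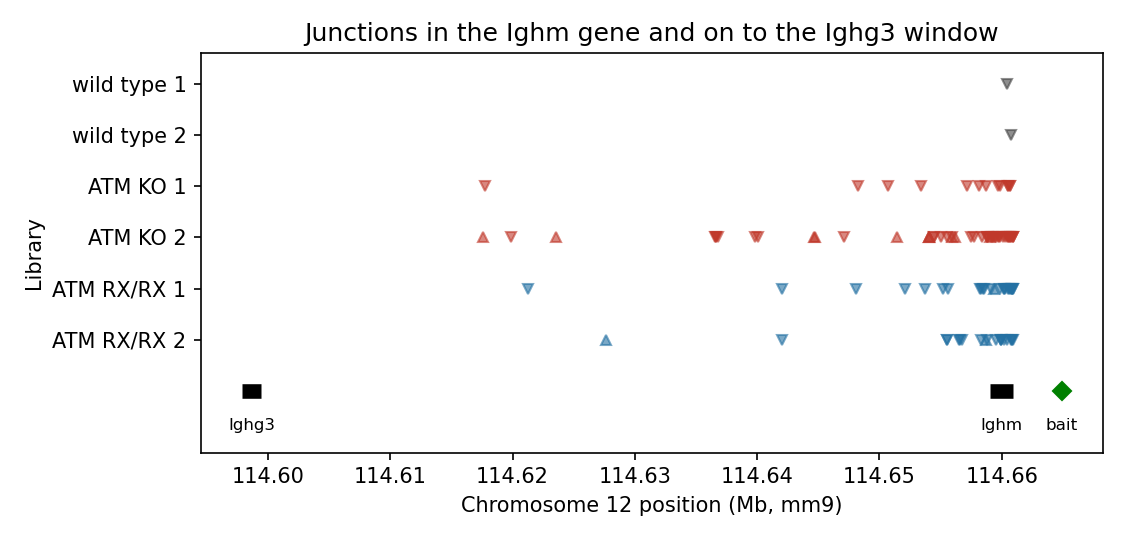
Junctions mapped in mm9 on chromosome 12 (x axis, Mb) between the Ighg3 window and the Ighm gene, 1 row per library (y axis), with downward triangles for the minus and upward triangles for the plus orientation. Black boxes are the Ighg3 and Ighm constant genes and the diamond is the bait primer; each wild-type library has 1 junction here, and the mutant libraries have 13 to 50.

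Switch acceptors that this stimulus does not target were rare in all groups. Outside the Sμ, Sγ1 and Sε lists, prey matched to Ighg3 or its upstream window made up 0.139% and 0.767% of IgH junctions in the wild-type libraries, 0.671% and 0.698% in ATM KO, and 0.351% and 0.387% in ATM RX/RX. For Ighg2b the shares were 0.555% and 1.28% in wild type, 2.35% and 0.768% in ATM KO, and 0.702% and 0.387% in ATM RX/RX. Ighg2c had between 0 and 6 junctions per library. Sα was not analysed here, as the annotation used places no Igha gene.

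Junctions outside IgH made up 21.6% ± 1.86 of all junctions in wild type, 28.1% ± 3.26 in ATM RX/RX and 25.0% ± 4.28 in ATM KO (SD, n = 2 each). The exact permutation p against wild type was 0.3333 for ATM RX/RX and 0.667 for ATM KO. Without ATM RX/RX replicate 1 the difference of that group was 4.26 points, against 6.57 with it. In ATM KO the higher mean rested on replicate 1 at 28.0%. Replicate 2, at 22.0%, lay between the wild-type libraries at 20.2% and 22.9%. In 4 libraries, 518 legible junctions off chromosome 12 could be placed in mm9, and 251 lay in a gene. Among the 17 off-target genes of the fixed list, 1 had legible junctions. Il4ra, which encodes the receptor chain for the IL-4 in the culture, on chromosome 7 from 132695785 to 132722986, had 12, all intronic. They came from wild-type replicate 1 (3), ATM RX/RX replicate 1 (3) and ATM RX/RX replicate 2 (6), and ATM KO replicate 1 had 0. Of the receptor loci, Igk had 2 legible junctions, Tcra 1, and Igl and Tcrb 0. Other genes named by the rule were Gpr84 with 11 junctions, B930007M17Rik and Cmah with 5 each, and Nr2e1 and Ubac2 with 3 each. Of those in Gpr84, 10 came from ATM RX/RX replicate 1, all at 1 coordinate, and 1 from ATM RX/RX replicate 2. Empty lines were left out of these counts, so a count of 0 is no limit on the gene.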

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

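The tests of list layout, region mix, bait proximity and orientation mix below were chosen only after the result was seen; those of repeated junctions and of positions were written down before.

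A second summary sheet in the workbook of ATM KO replicate 2, not used in the comparisons, drew attention because its Sγ1 share of IgH junctions was 47.1%, above both wild-type libraries. It counts 7121 junctions, 3.85 times the library's listed total, and gives Sμ 35.7% and Sε 14.2%. That Sμ share is close to wild type (33.0% and 35.5%) and runs against the 61.6% in the lists of ATM KO replicate 2. What it sums is not stated in the sources used here.

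The lower Sε share in ATM KO and ATM RX/RX was weighed against 2 technical explanations. Repeated copies of single junctions are argued against, since with 1 junction per coordinate and orientation the smaller difference from wild type was still -28.3 percentage points. The layout of the lists differs in wild-type replicate 1, but replicate 2 alone lay 19.45 points above the highest mutant library. A smaller Sε share with the ATM genotype may therefore be biological, as a hypothesis found and tested on the same data. A difference between animals or cultures stays open, as untested.

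The higher plus-orientation share was weighed in the same way. Repeated copies left a difference of at least 20.4 points. A changed mix of regions as the only source is argued against by Sμ alone, where the lowest mutant library lay 13.0 points above the highest wild-type library. The mix can still add to the pooled difference, which was 20.6 points in ATM KO, against 16.6 in Sμ, 11.3 in Sγ1 and 1.99 in Sε. In ATM RX/RX the pooled difference was 22.2 points, against 15.8, 16.7 and 13.7. Junctions near or upstream of the bait accounted for part of the Sμ difference in ATM RX/RX, which fell from 15.8 to 9.74 points without them. The remainder may reflect more inversions or joins between chromosomes in the mutants, which orientation alone cannot separate.

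Fewer blunt Sμ joints in the mutants formed the third pattern. The smaller difference was -13.8 points with 1 junction per coordinate and orientation, -12.6 points with positions weighted as in wild type, and -13.7 points among minus-orientation junctions. Each explanation predicted a difference above -5 points. A change in end joining with the ATM genotype may thus be the source, as a hypothesis, and differences between cultures stay open.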

How the results depend on the processing

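Alternatives that omit junctions near or upstream of the bait, DESeq2 on positions, the crossed pairing and wild-type replicate 2 alone were chosen after seeing the data; the others were fixed beforehand. The window near the bait was set after a first range had been tried; 200 bp to each side of the bait end is the one used. No difference between groups that did not overlap changed sign under any setting run. Leaving a library out could not turn such a sign, and the replicate block leaves a difference of group means unchanged. Only the other settings bear on the sign. Removing repeated coordinates or using the authors' own counts moved no leading difference by more than the spread between replicates. Repeated coordinates could not be removed for the share outside IgH, as 2 libraries had no list in use.

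Differences from wild type in percentage points moved as follows, and the cause was not tested except where the denominator itself changed. As percent of all junctions, the Sμ share difference was 15.4 for ATM RX/RX and 19.75 for ATM KO, and the Sγ1 difference between the mutants 3.96. As percent of the 3 regions the ATM KO Sμ difference was 31.9, and without junctions near the bait 29.7. Without junctions near or upstream of the bait the plus-share difference of ATM RX/RX was 18.5. For Sμ microhomology, ATM RX/RX gave 18.3 (2 bp or more), 5.29 (4 bp or more), 17.5 (no insertions), 17.0 (minus orientation) and 17.55 (away from the bait). ATM KO gave 16.7, 6.12, 15.8 and, away from the bait, 14.9. Over Sγ1 and Sε, 2 bp and 4 bp gave 23.2 and 10.9 for ATM RX/RX and 15.6 and 8.87 for ATM KO. At 4 bp the mutants differed by -0.824 in Sμ and 2.05 in Sγ1 and Sε.

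Counts past the threshold were less stable. For classes, ATM RX/RX (2) gave 1 with TMM factors and 5 with IgH totals, of which the classes outside IgH, still tested, are no part. Structure classes numbered 0 in DESeq2 for all 3 comparisons (7, 5 and 1 in edgeR); its mean dispersion of 0.151, taken without the 19 of 24 classes at its floor, exceeds the 0.00108 of edgeR. ATM KO structure gave 1 with minus-orientation junctions and 2 away from the bait, and the mutants 0 away from the bait. Positions (3 and 2) gave 1 and 1 with 200 bp bins, 0 and 0 with 1000 bp bins, 0 and 0 with DESeq2, and for ATM KO 0 with minus-orientation junctions. Leaving out 1 of the 4 libraries compared gave 0 to 3 classes for ATM RX/RX and 0 to 2 for ATM KO, 3 to 9 and 0 to 3 structure classes, 0 between the mutants, and 0 to 2 and 0 to 6 positions. Leaving out a library of the third group, which shares the fit, gave 2 and 3 classes, 6 and 7 structure classes (0 between the mutants), and 4 and 0 positions. A lone library was then assumed to vary like the other groups.

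Whether libraries of the same replicate number belong together is not known here. Deviations of same-numbered libraries correlated at 0.118 (ATM RX/RX and wild type), -0.852 (ATM KO and wild type) and -0.327 (the mutants). With 10 classes and 2 libraries per group, these values cannot decide it. With the replicate block, classes numbered 2 and 0, structure classes 6, 1 and 0, and positions 0 and 0. With crossed pairing of ATM KO, classes numbered 1 and 1, structure classes 8, 2 and 0, and positions 4 and 3. With Sε junctions as few as 17 in a library, depth limits what Sε can show.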

Other observations

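The bait part of the reads carried few base changes, a measure added after the data were seen. The authors' counts give 0.465% and 0.340% of bait bases changed in the wild-type libraries, 0.319% and 0.248% in ATM KO, and 0.348% and 0.330% in ATM RX/RX. The 95% Clopper-Pearson intervals of wild-type replicate 1 (0.334 to 0.630) and ATM KO replicate 2 (0.199 to 0.306) did not overlap, while wild-type replicate 2 (0.205 to 0.531) overlapped every mutant library. Within Sμ, insertions of 5 bp or more made up 4.89% ± 0.810 of junctions in wild type, 10.95% ± 2.63 in ATM KO and 9.16% ± 0.956 in ATM RX/RX (SD, n = 2 each), a minimum length chosen after the data were seen. The exact permutation p against wild type was 0.3333 for each mutant. Fisher's exact test separated 2 of 4 library pairs for ATM KO and 0 of 4 for ATM RX/RX. Insertions of any length made up 17.5%, 19.2% and 17.3% of Sμ junctions in the same order. Plus-orientation junctions upstream of the bait made up 3.57% ± 2.08, 8.65% ± 3.16 and 13.1% ± 3.01 of Sμ junctions in the same order, also a measure chosen after the data were seen.

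The hypotheses that follow were written down before their tests were run. If plus-orientation joins relied more on microhomology, its share would be higher among plus than minus Sμ junctions, but this was so in 0 of 6 libraries. In wild-type replicate 1 the shares were 55.9% (plus) and 58.7% (minus), and in ATM RX/RX replicate 1 they were 67.7% and 75.2%. A shift of Sγ1 junctions towards Sμ in the mutants would raise the median Sγ1 coordinate in every mutant library above both wild-type libraries. It did so in 3 of 4 libraries, which leaves that hypothesis undecided, since the prediction asked for 4 and its opposite for at most 2.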
